A study of Mus musculus with 6 samples.

How the data were processed

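The deposited data are tables of read counts per Ensembl gene ID, 1 per library, for 3 control and 3 Sox10ko cultures of the mouse Schwann cell line Msc80. Per the labels' protocols, cells were grown in serum-containing medium, total RNA was extracted with a column kit, and libraries were made with a stranded mRNA kit. The series design text names an Illumina HiSeq sequencer. Per the submitters' processing notes, STAR 2.6.0c, HTSeq and DESeq2 were used with the mouse build mm10 (GRCm38). The roles of these tools, the annotation release, the strand setting of the counting and any filters are not given in the sources used here. The counts were deposited as whole numbers that sum to a different total in each library, so they are raw counts. They are not corrected for gene length, and reads that fall on near-identical genes may be lost or misplaced. Because the strand setting is not stated, overlapping antisense genes are uncertain.

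Samples were grouped by their titles and genotype labels. Gene symbols matched 54042 of 54109 IDs. Coordinates and chromosomes came from GENCODE M21 on GRCm38, the build named by the submitters. Total counts ran from 32328618 to 41834431 per library, so that 1 read was worth between 0.0239 and 0.0309 CPM. Reads without molecular identifiers are not independent molecules, and intervals and floors cover counting error only. No pair of replicates agreed within sampling noise: the chi-square statistic per degree of freedom between replicates lay between 27.7 and 60.3 in control and between 78.8 and 91.1 in Sox10ko.

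Genes were filtered with filterByExpr of edgeR 4.0.16, scaled with TMM and tested with its quasi-likelihood F test (glmQLFit and glmQLFTest, R 4.3.3) for genotype, with all 6 libraries and no covariate. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 15427 tested genes, and 0.05 was the threshold. Gene lists and chromosomes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, and again with an estimated correlation. The 22 lists covered myelin, known Sox10 targets, Schwann cell transcription factors, other SOX genes, the node of Ranvier, immature and repair Schwann cells, neural crest and melanocytes, growth factor receptors, basal lamina and integrins, fibroblasts and collagens, smooth muscle, neurons, leukocytes and endothelium, epithelium, cholesterol and lipid synthesis, proliferation, the p53 response, the interferon response, Hedgehog, Notch and BMP signalling, Wnt signalling, mitochondrial transcripts, and immediate early and stress genes. Lists with fewer than 5 tested genes had no set test. Where a group had 0 reads of a gene, the fold is a lower bound against 3 counts over that group. With 1 to 3 reads it is the ratio of pooled CPM with an exact (Clopper-Pearson) 95% interval.

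The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Sox10, the 12 largest falls and the 12 largest rises among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted name, in each list up to 5 genes with the lowest adjusted p and up to 2 against its direction, and a few genes of known place in this field (Gldn, Nrcam, Nfasc, Sox2, Sox8, Sox9, Jun, Egr2, Pou3f1). The alternatives were DESeq2 size factors or library size alone for scaling, no low-count filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a replicate block, fry for the lists, and leaving out each library in turn. A GC offset per library and the removal of each library's chromosome medians were added after seeing the data. The edgeR step was tested on simulated data for Sox10ko against control, with counts drawn for 15427 genes and 50 genes changed at each fold. It recovered 4% of genes changed 1.5-fold, 74% at 2-fold, 92% at 4-fold and 100% at 8-fold, with 11 false calls among 15227 unchanged genes. Far fewer genes were changed there than the 4939 called in the data, which makes the adjusted threshold stricter. These shares are thus not those of the real comparison. The changed genes were drawn only from those with a mean over 1 CPM, so the shares do not cover genes near the floor. In the set test, a list of 25 genes shifted 2-fold was called and 0 of 100 unshifted random lists were. Genes were drawn independently of each other there, so false calls of lists with correlated genes were not tested. In the data, the estimated correlation of a list ran from -0.111 (SOX genes) to 0.650 (cholesterol and lipid synthesis).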

Results

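Messenger RNA was profiled in 6 cultures of Msc80, a mouse line of Schwann cells, the glia that wrap and support axons in peripheral nerves. In 3 of them the line carried an intact Sox10 gene (control). The other 3 had Sox10 inactivated by CRISPR/Cas9 editing (Sox10ko). The gene encodes a transcription factor of neural crest and glial cells. The labels call the cultures of a group biological replicates. They speak of a cell clone for each Sox10ko culture but do not say whether the 3 came from 1 clone or several, so an effect of Sox10 loss and a difference between clones are not separated by this design. The control libraries held 37473994, 40014020 and 41834431 counted reads and the Sox10ko libraries 32328618, 41529422 and 40176633. Levels are given as CPM, read counts scaled to a common library size after TMM normalisation, as mean ± SD with n = 3 per group, and fold changes as log2 of Sox10ko over control ± SE. The series was set up to find genes that depend on Sox10 in this line, and it holds a single comparison, Sox10ko against control.

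Sox10 itself (ENSMUSG00000033006) lies on the minus strand of chromosome 15 from 79154908 to 79165240 in GRCm38, where the annotation gives it 4 transcripts of 2 to 5 exons and 3051 exonic bases. It was read at 606, 627 and 617 CPM in control replicates 1, 2 and 3 and at 82.3, 67.5 and 116 CPM in Sox10ko replicates 1, 2 and 3. The Sox10ko libraries therefore kept 13.3%, 10.9% and 18.9% of the control mean. The fall of 6.95-fold was larger than the spread between replicates (log2 fold change -2.80 ± 0.20, edgeR adjusted p = 0.000186). Counts per gene do not show which exons the remaining 2746, 2874 and 4671 reads came from.

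Loss of Sox10 went with a near-complete loss of several transcripts typical of Schwann cells. Ngfr, the low-affinity neurotrophin receptor, dropped from 2965 ± 272 to 16.4 ± 13.4 CPM. Erbb3, the neuregulin receptor on which Schwann cell survival depends, went from 423 ± 44.3 to 2.61 ± 1.24 CPM. In the opposite direction, transcripts that were close to absent from the controls became abundant, among them Acta2 (smooth muscle actin) at 357 ± 270 CPM and Krt7 (a keratin of simple epithelia) at 91.1 ± 16.0 CPM.

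**Figure D1:**
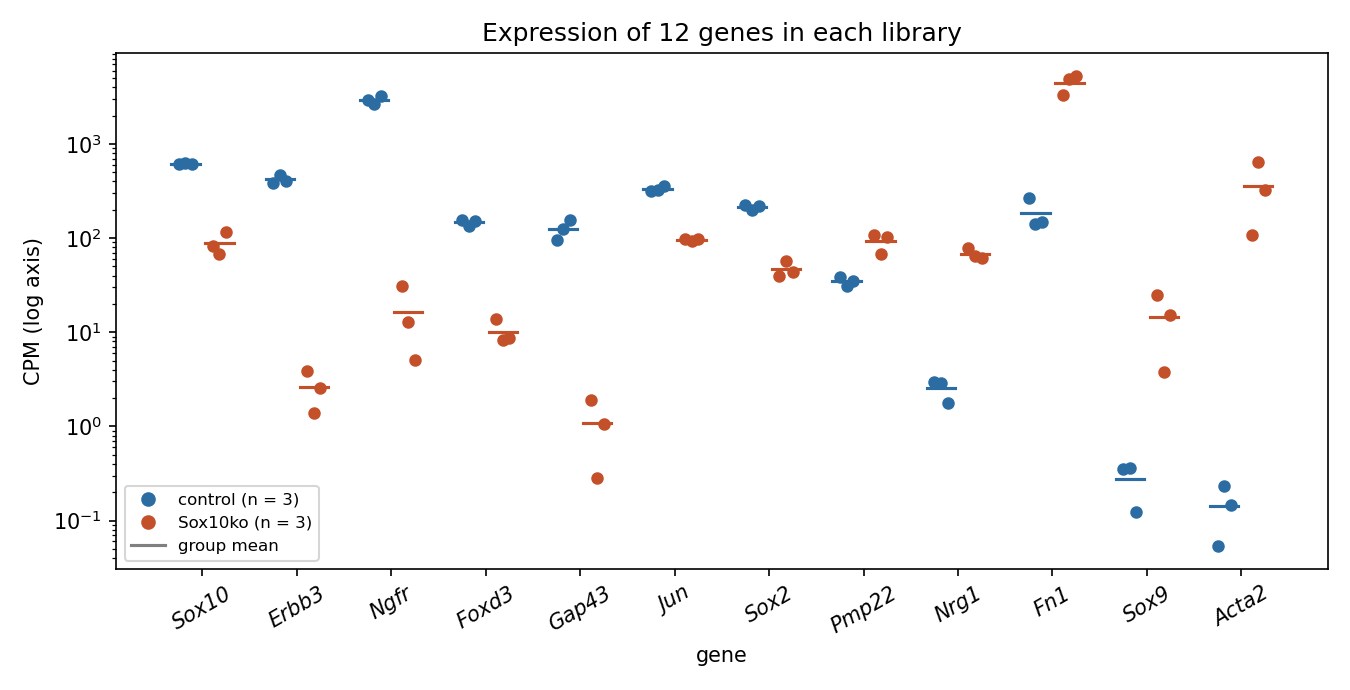
CPM on a log axis of 12 genes in each of the 3 control (blue) and 3 Sox10ko (orange) libraries, with a line at each group mean. Sox10, Erbb3, Ngfr, Foxd3, Gap43, Jun and Sox2 lie lower in all 3 Sox10ko libraries, and Pmp22, Nrg1, Fn1, Sox9 and Acta2 lie higher in all 3.

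Across the transcriptome, 15427 of the 54109 listed genes had enough reads to be tested, and 4939 of them differed between the groups, 2664 higher and 2275 lower in Sox10ko (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were seen for 2639 genes, 1699 higher and 940 lower. At an unadjusted p under 0.05 there were 6684 genes. In 7602 genes (49.3%) the control and the Sox10ko values did not overlap, where chance gives 10%. The count of changed genes was 2910 without control replicate 3. The Sox10ko libraries also varied more among themselves: over the 10236 genes with a mean of at least 5 CPM, the median SD of log2 CPM was 0.119 in control and 0.178 in Sox10ko.

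The 12 largest falls among genes with a mean of at least 5 CPM included those of Ngfr and Erbb3. Apod, a lipid-binding apolipoprotein made by Schwann cells, fell from 213 ± 40.0 to 0.271 ± 0.119 CPM (log2 fold change -9.62 ± 0.31, edgeR adjusted p = 1.14e-05). Gjc3, a connexin of myelinating glia, fell from 164 ± 52.4 to 0.213 ± 0.103 CPM (-9.60 ± 0.41, edgeR adjusted p = 3.39e-05). Gas7 fell 361-fold from 730 ± 141 CPM, and Nfasc (neurofascin, an adhesion molecule of the node of Ranvier) fell 230-fold. The potassium channel gene Kcna1 dropped 531-fold and Tmem132e 250-fold. Fxyd3 had 1368 reads in control and 2 in Sox10ko, a ratio of 680 with a 95% counting interval of 188 to 5617. Chn2 and the globin gene Hba-a1, which shares reads with a near-identical copy and is uncertain for that reason, fell 187-fold and 414-fold. Single libraries moved several of these sizes: without Sox10ko replicate 2, Nfasc fell 635-fold, Fxyd3 had a ratio of 430, and Chn2, with all 7 of its Sox10ko reads there, was at least 253-fold lower. Hba-a1 fell 1425-fold without Sox10ko replicate 3, and Ngfr 329-fold without replicate 1 against 181-fold with it. Padi2 was left with 1 read against 1230 in the controls, a ratio of 1222 with a 95% counting interval of 219 to 48303; without Sox10ko replicate 2, which held that read, it was at least 258-fold lower.

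Among the 12 largest rises, several genes had no control reads at all, and their folds are lower bounds set against a floor of 3 counts over the control group. Dlx3, a homeobox gene, was at least 850-fold higher in Sox10ko, Fam167a at least 639-fold, the nuclear receptor gene Esrrb at least 539-fold, and P2rx1, an ATP-gated channel, at least 981-fold. Pcp4 was at least 469-fold higher, but its call was lost without control replicate 2 (edgeR adjusted p = 0.0512) or without control replicate 3 (edgeR adjusted p = 0.0568, the highest of all alternatives, against a lowest of 9.63e-06 with DESeq2). The Sox10ko libraries disagreed on the size of some of these rises: P2rx1 stood at 4.70, 56.4 and 9.10 CPM in replicates 1, 2 and 3. Without Sox10ko replicate 2 the bound was 277-fold for P2rx1 and 332-fold for Esrrb, and without replicate 3 it was 94.3-fold for Pcp4, with 1213 of its 1397 reads there. Leaving out control replicate 3 lowers every bound, to 552-fold for Dlx3 and 415-fold for Fam167a, since fewer control reads are then set against the floor. Fam167a was even across them, at 15.5, 15.4 and 18.2 CPM. Krt7 had 3 reads in control and 10553 in Sox10ko, a ratio of 3541 with a 95% counting interval of 1211 to 17173, and 2357 to 6896 with 1 control library left out (control replicates 2 and 3). Krt80 rose from 0.0334 ± 0.0289 to 90.5 ± 20.3 CPM and Lrrc32, a receptor that holds latent TGF-beta, from 0.0438 ± 0.0325 to 209 ± 130 CPM. Masp1 rose 669-fold, or 330-fold without Sox10ko replicate 1, and Lrrc32 rose 8343-fold without control replicate 1 against 4766-fold with it. Slc6a12 and Iqsec3 had 1 control read each, for ratios of 1336 (95% counting interval 239 to 52798) and 1519 (272 to 60034). Without the control library that held the read they were at least 296-fold and 346-fold higher, and Iqsec3 had a ratio of 667 without Sox10ko replicate 2.

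Myelin genes changed mostly downwards where they changed. Of 18 tested genes of the myelin list, 8 were lower and 1 was higher in Sox10ko, and adjusted over the list alone 9 were lower and 3 higher (median log2 fold change -0.50). The set test passed (limma camera adjusted p = 0.00335) and was lost with an estimated correlation (limma camera adjusted p = 0.145) or a mean of at least 5 CPM (limma camera adjusted p = 0.0505). The falls included that of Gjc3. Pmp22, the gene of a compact myelin protein, rose from 35.1 ± 3.87 to 92.5 ± 21.6 CPM (log2 fold change 1.40 ± 0.19, edgeR adjusted p = 0.00184). Of 17 tested genes listed beforehand as known Sox10 targets, 10 were lower and 2 higher, over the list alone 10 and 3 (median -1.74, or -3.81 with a mean of at least 5 CPM; limma camera adjusted p = 0.000389, and adjusted p = 0.166 with an estimated correlation). Lgi4, a secreted protein needed for Schwann cell maturation, fell 134-fold, or 210-fold without Sox10ko replicate 3. Cx3cl1, a chemokine gene, was the other exception next to Pmp22, with 3 control reads against 215 in Sox10ko, a ratio of 72.1 and a 95% counting interval of 24.4 to 353 (46.8 without control replicate 3 and 144 without control replicate 2).

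Transcription factors of the Schwann cell lineage fell as a group: 15 of 25 tested were lower and 3 higher, with the same counts over the list alone (median log2 fold change -0.58; limma camera adjusted p = 0.000231, and adjusted p = 0.0873 with an estimated correlation). Foxd3, a neural crest factor, fell from 147 ± 11.2 to 10.2 ± 3.07 CPM, Notch1 from 208 ± 23.6 to 15.8 ± 6.61 CPM, and Jun, a central factor of the injury response, from 332 ± 20.7 to 95.8 ± 2.30 CPM. Nab2, a corepressor of Egr proteins, rose 2.27-fold. Egr2, the master regulator of myelination, was low in both groups at 3.40 ± 0.752 and 2.26 ± 0.855 CPM and did not pass (edgeR adjusted p = 0.239). Pou3f1 had 0 reads in control and 1 in Sox10ko and was not tested. Among other SOX genes, 5 of 7 tested were lower and 2 higher, in all genes and over the list alone (median -1.09; limma camera adjusted p = 0.0444, and adjusted p = 0.174 with an estimated correlation). This set call was also lost without Sox10ko replicate 2 (limma camera adjusted p = 0.0579) or 3 (limma camera adjusted p = 0.0527). Sox6 fell 10.1-fold, Sox13 17.5-fold and Sox2, a marker of immature Schwann cells, 4.61-fold. Sox9 rose from 0.278 ± 0.135 to 14.6 ± 10.6 CPM (52.6-fold, or 34.2-fold without Sox10ko replicate 1), and Sox8, of the same subgroup as Sox10 and Sox9, from 1 read to 69, a ratio of 69.5 with a 95% counting interval of 12.1 to 2783, and at least 15.8-fold higher without control replicate 1, which held that read.

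Genes of immature and repair Schwann cells were lower too, 14 of 25 tested against 3 higher, and 16 and 3 over the list alone (median log2 fold change -0.65; limma camera adjusted p = 0.000389, and adjusted p = 0.0873 with an estimated correlation). Gap43, a growth-associated protein, fell from 126 ± 29.6 to 1.09 ± 0.818 CPM (115-fold, or 186-fold without Sox10ko replicate 1), the peptide hormone gene Ucn2 16.3-fold and the cytokine gene Lif 7.17-fold. The growth factor genes Nrg1 and Bdnf went the other way, Nrg1 from 2.54 ± 0.683 to 67.9 ± 9.29 CPM and Bdnf from 4.45 ± 0.403 to 17.2 ± 2.43 CPM. Growth factor receptors were lower in 9 of 21 genes and higher in 3, with the same counts over the list alone. Their median was -0.46, or -0.22 with chromosome medians removed per library. The set passed (limma camera adjusted p = 0.0202), and did not with an estimated correlation (adjusted p = 0.145) or a mean of at least 5 CPM (adjusted p = 0.0542). Next to Ngfr and Erbb3, Gfra1 (a GDNF co-receptor) fell 4.46-fold and Met (the hepatocyte growth factor receptor) 4.41-fold, while Fgfr3 rose from 1.31 ± 0.247 to 16.0 ± 6.05 CPM.

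Genes of the node of Ranvier and axoglial contact changed in both directions, 8 lower and 3 higher of 26 tested (9 and 4 over the list alone), and the set did not pass (limma camera adjusted p = 0.165). Its median was 0.03 (-0.08 with a mean of at least 5 CPM) and its mean -0.74 on the log2 scale, and the test pointed down. Besides Nfasc, large falls were those of Gldn (gliomedin), which went from 23.3 ± 7.74 to 1.31 ± 1.61 CPM (edgeR adjusted p = 0.0112, 17.8-fold, or 59.9-fold without Sox10ko replicate 3), and of the adhesion molecule Nrcam, 7.30-fold (edgeR adjusted p = 0.000117). Neural crest and melanocyte genes were split as well, 5 lower and 4 higher of 11, in all genes and over the list alone (limma camera adjusted p = 0.513, direction down where the median of 0.05 and the mean of 0.09 were up). Ets1 fell 3.56-fold and Msx2 rose 2.15-fold.

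Genes of the matrix that surrounds the cells changed in both directions, and neither of their lists passed as a set. Of 29 basal lamina and integrin genes, 11 were lower and 8 higher (12 and 10 over the list alone), with a median of 0.00 (limma camera adjusted p = 0.439). Fn1 (fibronectin) rose from 185 ± 70.1 to 4479 ± 1030 CPM (24.2-fold, edgeR adjusted p = 0.000179) and the integrin gene Itgb5 6.89-fold. Nid1 (nidogen, a linker of basement membranes) fell from 267 ± 91.9 to 10.7 ± 2.32 CPM, Itga1 7.07-fold and Lama4 9.23-fold. Fibroblast and collagen genes were higher in 7 and lower in 3 of 19 (9 and 3 over the list alone; limma camera adjusted p = 0.210), with Mfap5 221-fold higher (135-fold without Sox10ko replicate 1 and 441-fold without control replicate 2), Loxl1 46.2-fold higher and Postn (periostin) 35.5-fold lower.

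Contractile genes of smooth muscle rose together. Of 12 tested, 10 were higher and 0 lower, 11 and 0 over the list alone (median log2 fold change 3.24; limma camera adjusted p = 1.75e-06, and adjusted p = 0.145 with an estimated correlation). Desmin (Des) rose from 0.384 ± 0.0534 to 18.8 ± 8.47 CPM, Tpm2 20.3-fold, and the actin-binding genes Cnn2 and Cald1, already abundant in control, 6.43-fold and 3.15-fold. Acta2 stood at 107, 644 and 321 CPM in Sox10ko replicates 1, 2 and 3, against at most 0.231 CPM in a control library, and rose 2486-fold, or 1490-fold without replicate 2. Acta2 and Tpm2, with 17 and 23 control reads, passed the low-count filter only through the Sox10ko libraries, so their direction was set by it.

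Proliferation genes were modestly lower: 15 of 30 fell and 0 rose, 23 and 0 over the list alone (median log2 fold change -0.49; limma camera adjusted p = 1.75e-06, and adjusted p = 0.413 with an estimated correlation). Mcm7, a subunit of the replicative helicase, fell 1.79-fold and the mitotic motor Kif11 1.94-fold, and Mki67 fell from 1285 ± 120 to 777 ± 128 CPM. Genes of the p53 response were higher in 11 of 22 and lower in 0, with the same counts over the list alone (median 0.76; limma camera adjusted p = 0.000345, and adjusted p = 0.145 with an estimated correlation). Fas, a death receptor, rose 19.7-fold and Gdf15, a stress cytokine, 116-fold, while the polymerase gene Polk rose 2.06-fold. Interferon response genes were higher in 14 of 19 and lower in 0, 16 and 0 over the list alone (median 2.05, or 0.87 with a mean of at least 5 CPM; limma camera adjusted p = 1.40e-05, and adjusted p = 0.0873 with an estimated correlation). Usp18 rose 26.0-fold and Gbp2 6.01-fold. Immediate early and stress genes were higher in 6 and lower in 1 of 18, also over the list alone, and did not pass as a set (limma camera adjusted p = 0.140).

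Other pathways did not pass as sets. Hedgehog, Notch and BMP genes were higher in 5 and lower in 5 of 19 (7 and 5 over the list alone; limma camera adjusted p = 0.987), with the Hedgehog receptor gene Ptch1 2.71-fold lower and its transcription factor gene Gli1 2.78-fold higher. Wnt genes were higher in 7 and lower in 1 of 16, also over the list alone (limma camera adjusted p = 0.101, and adjusted p = 0.0480 without control replicate 1); the receptor gene Fzd2 rose 2.62-fold. Cholesterol and lipid synthesis genes were higher in 3 and lower in 1 of 30 (1 and 0 over the list alone; limma camera adjusted p = 0.513, and adjusted p = 0.00565 without Sox10ko replicate 2), and Hsd17b7 rose 3.42-fold.

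Markers of further cell types were mostly at low levels in both groups. Of 4 epithelial genes tested, all 4 were higher in Sox10ko, too few for a set test. Of these, Krt7, Krt14 and Krt8 had 3, 9 and 9 control reads and passed the low-count filter only through the Sox10ko libraries. Their direction was thus set by the filter. The untested genes of the 15 listed had at most 32 reads each over all 6 libraries, with 1 for Epcam and 14 for Cdh1. Krt7 reached 91.1 CPM in Sox10ko, and Krt14, Krt8 and Muc1 reached 1.91, 1.56 and 1.25 CPM. Krt8 and Muc1 were no longer called without control replicate 1 (edgeR adjusted p = 0.0542 and 0.0737) or 3 (edgeR adjusted p = 0.0628 and 0.0875), and Muc1 also without Sox10ko replicate 1 (edgeR adjusted p = 0.0514). Leukocyte and endothelial genes were higher in 3 and lower in 1 of 6, also over the list alone (limma camera adjusted p = 0.449), with Lyz2 rising to 10.7 ± 3.38 CPM and Vwf to 31.7 ± 20.6 CPM (16.7-fold, or 10.5-fold without Sox10ko replicate 3). Neuronal genes were lower in 2 of 8 and higher in 0, also over the list alone; the set did not pass (limma camera adjusted p = 0.539) and its median of 0.51 and mean of -0.51 differed in sign, with Gap43 at -6.89. The 13 mitochondrially encoded genes of the RNA quality list were not analysed here, as 0 of them are among the listed genes. In all, 10 of 20 lists passed with the preset correlation, 3 higher and 7 lower, and 0 passed with an estimated one. Among these 10, the estimate lay below the preset 0.01 for Schwann cell transcription factors (-0.014) and SOX genes (-0.111). It also did for immature and repair Schwann cells (-0.003) and growth factor receptors (-0.029), so a higher correlation did not remove these calls. For the other lists that passed it lay above the preset, from 0.013 for myelin and 0.016 for the interferon response up to 0.563 for proliferation. For myelin and the interferon response it was thus close to the preset. Why the calls were lost in these lists was not tested.

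**Figure D2:**
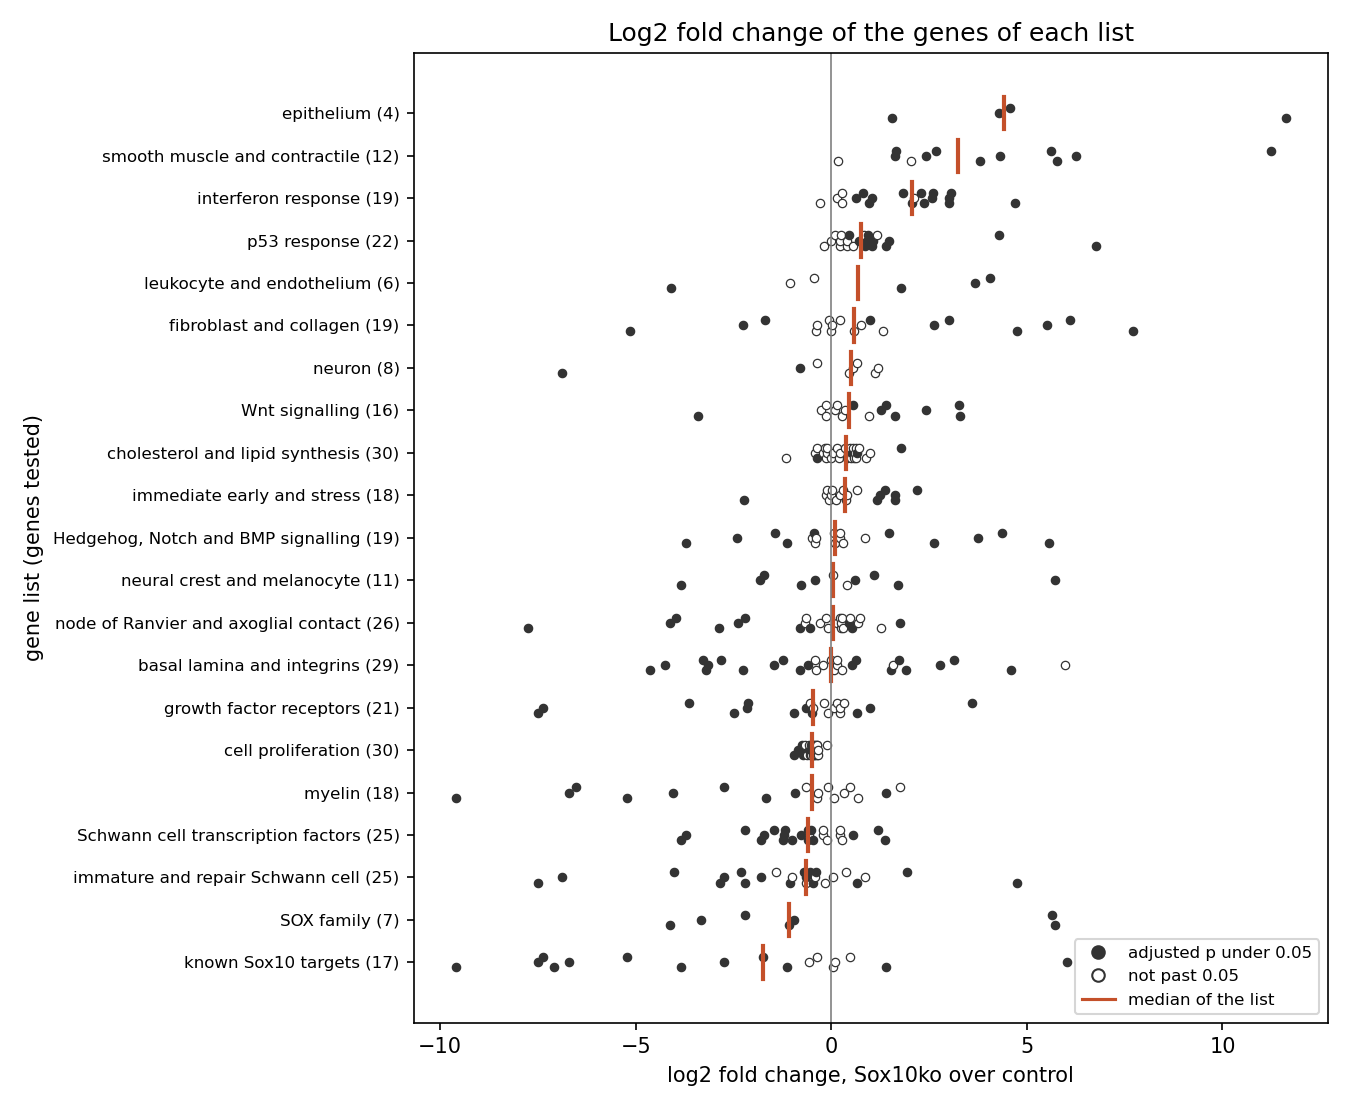
Log2 fold change of Sox10ko over control (horizontal axis) for the tested genes of each list (rows, with the number tested), filled where the edgeR adjusted p is under 0.05 and open where not, with the median of each list as an orange bar. The medians run from -1.74 for known Sox10 targets to 4.42 for the 4 epithelial genes.

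By chromosome, genes were lower in Sox10ko as a set on chromosome 14 and on none of the other 19 tested (limma camera adjusted p = 0.0127, and adjusted p = 0.978 with an estimated correlation). There the median log2 fold change of 508 genes was -0.24, with 54 genes higher and 113 lower. The median was -0.20 without control replicate 2 and -0.15 without Sox10ko replicate 3. The call was lost without control replicate 2 (limma camera adjusted p = 0.0877) and without Sox10ko replicate 3 (limma camera adjusted p = 0.129). Chromosome 17 passed upwards without Sox10ko replicate 1 or 2 (limma camera adjusted p = 0.0176 and 0.0382), chromosome 6 without replicate 1 (limma camera adjusted p = 0.0344) and chromosome 5 downwards without replicate 2 (limma camera adjusted p = 0.0382). Single libraries were set apart on single chromosomes by more than this: relative to the mean of the controls and to each library's own median over all genes, genes of chromosome 18 lay at -0.36 in Sox10ko replicate 1, those of chromosome 15 at -0.41 in replicate 2 and those of chromosome 14 at -0.42 in replicate 3. Control replicate 2 lay at -0.30 on chromosome 1, relative to the other controls.

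**Figure D3:**
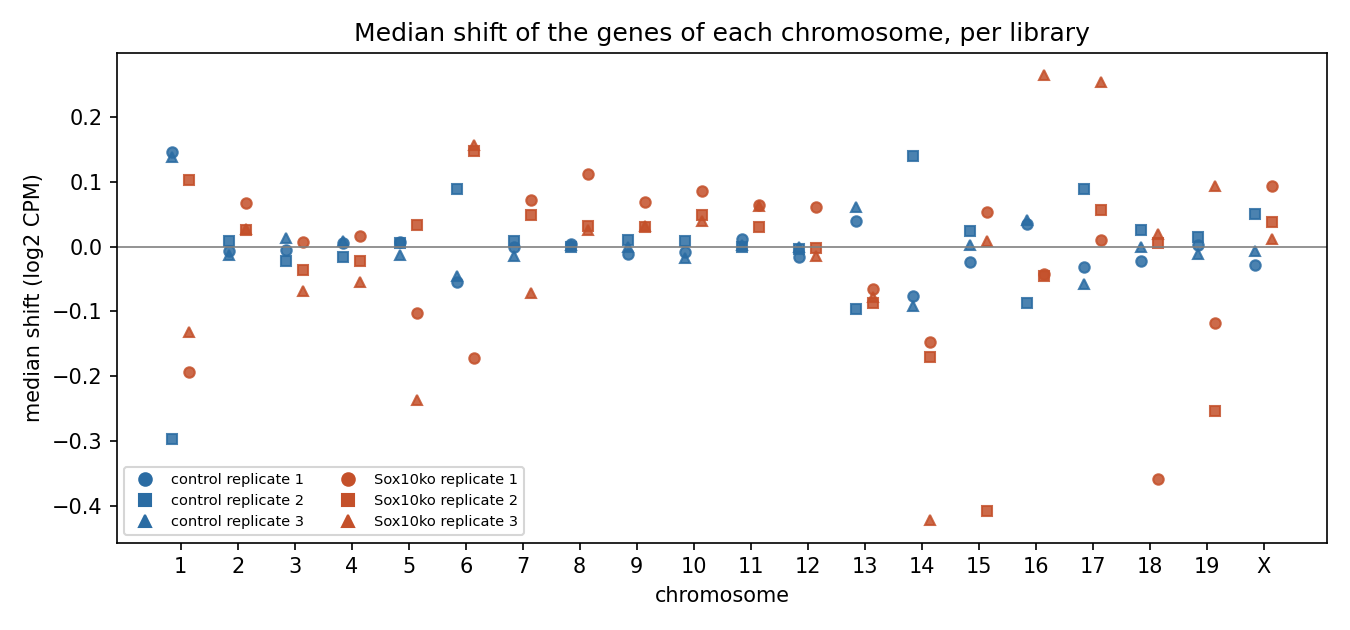
Median shift in log2 CPM (vertical axis) of the genes with a mean of at least 5 CPM on each chromosome (horizontal axis), for each of the 6 libraries against the mean of the controls (for a control library, of the other 2), after subtracting the library's median over all genes. Sox10ko replicates 1, 2 and 3 reach -0.36 on chromosome 18, -0.41 on chromosome 15 and -0.42 on chromosome 14.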

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

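Alternatives added only after the results were seen were the GC offset and the removal of chromosome medians. Sox10 fell under every alternative run, and the count of changed genes stayed within 1.5 times of 4939 in all of them but one: leaving out 1 library gave 2910 to 4540, the lowest without control replicate 3, and fewer samples enter each of these fits. The count of at least 2-fold changes was 1222 with a mean of at least 5 CPM, where 10235 genes were tested, and 2011 to 2574 with 1 library left out. With the replicate block there were 3537 changed genes and 2317 at least 2-fold; the deviations of same-numbered libraries from their group means correlated at -0.119, -0.042 and 0.035, and 1 of 6 libraries correlated best with its own number, so the numbers do not pair the cultures. DESeq2 called 5690 genes and limma-voom 4859. Of 20 lists, 0 passed with an estimated correlation, 17 with directional fry and 19 with mixed fry, which ask a different question from camera; leaving out 1 library gave 9 to 11. For chromosomes, the estimated correlation gave 0, and leaving out 1 library gave 0 (control replicate 2 or Sox10ko replicate 3) to 3 (Sox10ko replicate 1 or 2). Of 147 named genes 134 passed as reported, 118 of these kept direction and call in all 15 alternatives that could test them, and 16 lost the call in at least 1. Direction was reversed only for 3 genes that did not pass as reported: Mal, at 1.75, ranged from -1.29 (without Sox10ko replicate 1) to 2.30 with 1 library left out; Ano3, at -0.01, gave 0.0543 by library size alone, 0.0422 with a mean of at least 5 CPM, 0.0963 with the GC offset, 0.0025 with chromosome medians removed, and -0.70 to 0.28 with 1 library left out; Actb, at 0.01, gave -0.0308 with no low-count filter, -0.0381 with the GC offset, and -0.0549 to 0.0987 with 1 library left out. The cause was not tested. Depth limits genes near the floor, such as Pou3f1.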

Other observations

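Tests chosen only after the result was seen were those of gene families and of the genes around Sox10, those of unedited cells, fibroblasts and actin reads, and that of a single region in Sox10ko replicate 3. Besides the listed pathways, 11 of 214 gene families held more 2-fold changes in one direction than other genes. The test counts the genes of a family as independent, so families whose members change together may pass too easily. Among these families of at least 8 tested genes that share a symbol stem (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted p), the Serpinb protease inhibitors had 8 of 11 genes at least 2-fold higher in Sox10ko (adjusted p = 0.000419). Serpinb6b rose from 0.136 to 6.83 CPM and Serpinb9 from 8.47 to 39.4 CPM. Serpinb9c, Serpinb9e, Serpinb9g and Serpinb6b, with 0, 2, 5 and 16 control reads, passed the low-count filter only through the Sox10ko libraries. They could thus only count as higher. Histone genes had 12 of 18 at least 2-fold higher (adjusted p = 8.51e-06), with Hist1h1c going from 2.61 to 20.3 CPM and Hist1h2bc from 3.83 to 16.7 CPM. Histone genes share reads with near-identical copies and are uncertain for that reason. Several of them also passed the filter only through Sox10ko, among them Hist1h4h, Hist1h2bg and Hist1h1e with 7, 9 and 10 control reads. These genes, and the others named in this part that the text had not named before, were chosen after their values were seen.

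Semaphorins, cadherins and integrin alpha genes passed in the lower direction and not in the higher (adjusted p = 1, 1 and 0.419). Of 19 semaphorin genes 7 were at least 2-fold lower (adjusted p = 0.00685), or 6 with scaling by library size alone, and 4 were at least 2-fold higher. Sema6d fell from 97.4 to 17.9 CPM and Sema4c by a log2 fold change of -2.06, while Sema3c rose from 48.5 to 212 CPM. Of 8 cadherins 4 were at least 2-fold lower (adjusted p = 0.0320) and 2 at least 2-fold higher: Cdh19, a cadherin of Schwann cell precursors, fell from 351 to 13.6 CPM and Cdh10 from 91.0 to 1.19 CPM (76.6-fold, or 195-fold without Sox10ko replicate 2). Of 12 integrin alpha genes 5 were at least 2-fold lower (adjusted p = 0.0278) and 4 at least 2-fold higher. Of 8 Ccl chemokine genes 4 were at least 2-fold lower (adjusted p = 0.0320), with Ccl7 going from 746 to 177 CPM, and of 14 Rgs genes of G protein regulation 5 were (adjusted p = 0.0347), with Rgs16 going from 549 to 64.2 CPM. The other families that passed were Krt (6 of 8 higher, adjusted p = 0.00471), Ifi (6 of 12 higher, adjusted p = 0.0320), Cyp (7 of 27 lower, adjusted p = 0.0320) and Sox (5 of 10 lower, adjusted p = 0.0117). In the other direction 1 Krt, 1 Ifi, 8 Cyp and 2 Sox genes changed at least 2-fold. More Cyp genes thus rose than fell (Fisher's exact test, adjusted p = 0.149 for the rise). The 5 lower Sox genes include Sox10, the edited gene, whose fall is no separate evidence, and the test was not run without it. The 6 Krt genes that rose had at most 9 control reads each, so they could be tested only through Sox10ko. So could Ifi47, Ifi205 and Ifi27l2a, with 9, 19 and 22 control reads. Genes nearly absent from Sox10ko, such as Ccl12 and Cyp3a16 with 0 reads there, could be tested only through the controls. The direction of all these genes was set by the filter, and the family tests rest in part on it. Within 300 kb of Sox10, 7 of 23 other tested genes were lower and 0 higher by edgeR, against 87 of 593 lower on the rest of chromosome 15 (Fisher's exact test, two-sided, p = 0.0674, from 0.00663 to 0.566 over the alternatives). Among them Micall1 fell from 75.5 to 38.5 CPM and H1f0 from 523 to 258 CPM.

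Sox10 reads remained in all 3 Sox10ko libraries. In the annotation 0 genes share exonic bases with Sox10 on the same strand, which argues against reads of an overlapping gene. Unedited cells in the Sox10ko cultures would bring every control transcript in at least the share that Sox10 kept, yet 21 of 2679 abundant genes lay below 0.5 times that share in each Sox10ko library, down to 0.128% of control for Apod and 0.554% for Ngfr. That bound was set after the value was seen and after 2 earlier bounds had not been met: the median share left over the 20 most abundant genes that fell at least 4-fold was 11.1% against a lowest Sox10 share of 10.9%, and the 21 genes were 0.784% of the abundant ones, under the 1% set. A transcript still made from an edited gene may explain these reads, a hypothesis that counts per gene do not test.

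Contractile genes rose with a median log2 fold change of 3.24. Fibroblasts mixed into the Sox10ko cultures cannot be told apart from a change of the edited cells. The median over Col1a1, Col1a2, Col3a1, Dcn and Lum was 0.762, taken as the log2 ratio of mean CPM plus 0.1. However, Dcn (8 and 21 reads) and Lum (6 and 17) lay near the floor, where the added 0.1 shrinks the ratio. By edgeR the median over the other 3 was 2.61, with Col1a1 at 2.61, Col1a2 at 3.02 and Col3a1 at 0.59 (not past in edgeR as reported, past in 7 of 15 alternatives). Reads shared between near-identical actin genes would give Acta2 0.29 CPM at the Sox10ko level of Actg1, where the lowest Sox10ko library had 107 CPM; the bound set before, no rise of Actb and Actg1, was not met, as Actg1 rose from 200 to 403 CPM (edgeR adjusted p = 0.00716). Fibroblasts, Sox10 loss and a difference between clones all stay open as explanations of the rise.

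Single libraries lay apart on single chromosomes, and the test with a GC offset argues against GC content of transcripts, as the largest shift of each Sox10ko library kept at least 0.866 of its size. In all 3 Sox10ko libraries it lay outside the range of 10000 random gene sets, and in Sox10ko replicates 1 and 2 all 4 of 4 stretches of the chromosome with equal numbers of tested genes shared it, against one region or gene cluster as the source. In Sox10ko replicate 3 only 2 of the 4 stretches of chromosome 14 did, at -1.01 and -0.92 against 0.02 and -0.07, as one region or gene cluster would give once the bound set before, 1 stretch, which was not met, was widened to 2 after the values were seen. The largest shifts of control replicates 1, 2 and 3, each against the other 2 controls, lay on chromosome 1 at 0.145, -0.297 and 0.138. They too lay outside the range of random gene sets, and all 4 stretches shared them. Such shifts were thus not particular to the Sox10ko cultures. Differences in chromosome number or segments between cultures may explain these shifts, a hypothesis found and tested on the same data, for which DNA was not measured.

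The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Every split but the real one puts control and Sox10ko libraries in both groups, so their difference adds to the spread within groups. Each group of such a split holds 2 libraries of 1 genotype and 1 of the other, so part of the difference also stays between the groups. A count of 0 changed genes there is therefore no measure of what like groups would give. As many changed genes were called by edgeR in 1 split, the real one (4939, highest other 0), as many at least 2-fold changes in 1 (2639, highest other 0), and as many gene lists in 1 (10, lowest other 3 and highest other 7). Lists thus passed in every split, also where 0 genes were called. As many chromosomes passed in all 10 splits (1 in the real one, highest other 9), several times the real count, which points to a structure of the samples or to a set test that passes too easily at the preset correlation; these were not separated.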
